A study of Mus musculus with 12 samples.

How the data were processed

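RNA from the cytoplasm of RAW mouse macrophages was measured in 12 samples: hnRNP K IP, Luciferase IP and input, each from untreated cells and from cells given LPS at 10 ng/ml for 6 h, with 2 samples per group. Per the labels' protocols, the co-purified or total RNA was isolated with Trizol, and biotin-labelled amplified RNA was prepared for the arrays. Groups and replicate numbers were taken from the sample titles.

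The deposited values were taken as log2 signals per probe set, and the submitters' processing notes name RMA without a log scale. RMA corrects the background of each probe, normalizes probe values between arrays and combines the probes of a probe set, and its output is on a log2 scale. The log base, the RMA version, and whether all 12 arrays were processed together are not given in the sources used here. The values ran from 0.88 to 14.65 with medians per array of 4.8 to 5.2, which fits a log2 scale and no linear one. Quantile steps inside RMA assume that samples share a distribution of signal, so a sample with little RNA can have its noise stretched towards the range of the others. No further normalization was applied in the planned fit. The share of probe sets above 8 was 16.7 to 17.9% on the input arrays and 14.6 to 16.7% on the hnRNP K IP arrays. It was 12.9 and 10.7% on the untreated Luciferase IP arrays, and 7.30 and 4.65% on those after LPS.

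Of 45037 probe sets, 34945 were paired with 1 gene symbol by the platform annotation, 932 with several and 9160 had none listed; the last 2 kinds were left out of gene tests. Each gene was represented by its probe set with the highest mean over the 12 arrays, which gave 18193 genes, of which 18145 symbols were found in the RefSeq gene table used here. Probe sets of a gene can disagree, as is given for Map3k7.

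Groups were compared with limma 3.58.1 in R 4.3.3. A mean per group was fitted to all 12 arrays with 6 residual degrees of freedom, and moderated tests were made with eBayes and Benjamini-Hochberg adjustment over the genes at a threshold of 0.05. The 9 comparisons were hnRNP K IP against Luciferase IP in each condition, the change of that difference with LPS, LPS against untreated input, hnRNP K IP against input in each condition and its change with LPS, and Luciferase IP against input in each condition. The first 4 were the main comparisons. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists of a comparison, and again with an estimated correlation and with fry. The lists held 678 genes, of which 592 were measured.

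The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Map3k7 and Hnrnpk in every comparison, the 8 genes at each end among those called and with no overlap between the arrays of both groups in a main comparison (3 in the others), and up to 3 called members per list in the main comparisons; genes without an established name were left out. The lists were cytokines and chemokines, interferon response, NF-kB targets and feedback regulators, TLR4 and TAK1 signalling, macrophage identity, markers of other cell types, nuclear-retained RNAs, heat shock and immediate early genes, ribosomal proteins, translation factors, oxidative phosphorylation, proteasome, lysosome, endoplasmic reticulum folding, glycolysis, cholesterol biosynthesis, cell cycle, hnRNP and poly(C)-binding protein mRNAs, mRNA stability regulators, chromatin and transcription regulators, and published hnRNP K-bound mRNAs.

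The alternatives fixed in advance were quantile normalization of the probe set values, centring of each array, only genes above the median level, the mean of a gene's probe sets, leaving out probe sets prone to cross-hybridization, an intensity trend in eBayes, only the arrays of the compared groups, at least a 2-fold difference, the replicate number as a block, and leaving out each array. After the values were seen, a fit with array weights and a fit without the 4 Luciferase IP arrays, the latter also with the replicate number as a block, were added, and arrays outside a comparison were left out as well. arrayWeights gave 2.53 and 2.48 to the untreated and LPS hnRNP K IP arrays, 3.61 and 2.79 to input, and 0.201 and 0.0787 to Luciferase IP. A planned comparison of C-rich motifs in 3' untranslated regions was not run, since transcript sequences were not used here.

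The fits were tested on simulated data for all 18193 genes, with 100 genes changed at each of 2 sizes, 1 and 2 log2 units. The spread of each group was taken from the data. With so few changed genes the adjusted threshold is stricter than in a comparison with many differences, so the recovered shares need not hold there. Of genes changed by 2 log2 units, the planned fit recovered 20% for hnRNP K IP against Luciferase IP in untreated cells and 51% after LPS. For LPS against untreated input it recovered 0%, while the fit without Luciferase IP arrays recovered 93% of genes changed by 1 log2 unit and 100% of those changed by 2. For hnRNP K IP against input the planned fit recovered 0% in each condition, and the fit without Luciferase IP arrays 95 and 90% at 1 log2 unit in untreated and LPS cells.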

Results

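Cytoplasmic RNA of RAW cells, a mouse macrophage line, was measured on 12 Affymetrix arrays. RNA was taken either directly from the extract (input), from an immunoprecipitation (IP) of hnRNP K, an RNA-binding protein of the poly(C)-binding family, or from an IP with an antibody against Luciferase, which served as the control. Each kind of RNA came from untreated cells and from cells given lipopolysaccharide (LPS), a bacterial membrane component sensed by TLR4, at 10 ng/ml for 6 h. The 6 groups held 2 arrays each, which the series design describes as biological replicates. Values are RMA log2 signals per probe set, and 18193 genes were tested with limma. Differences below are log2 differences of group means (n = 2 arrays per group) with their standard error (SE). The SE rests on a spread per gene shared by all 6 groups and does not measure that of the compared groups alone. Every gene named for the size of its difference had both arrays of the higher group above both of the lower. Where a group mean lies below the lower quartile of its arrays, the signal was not shown to lie above background, and the size of the difference is called uncertain. With 2 arrays per group, the number of arrays limits the precision of every value.

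The Luciferase IP arrays stood apart from the other 8. The replicates correlated at r = 0.990 in hnRNP K IP of untreated cells, 0.990 after LPS, and 0.994 and 0.992 in input, against 0.860 in Luciferase IP of untreated cells and 0.568 after LPS. The range between the 5th and 95th percentile was 7.97 to 8.21 log2 units on the hnRNP K IP and input arrays, 7.06 and 6.79 on the untreated Luciferase IP arrays, and 5.79 and 4.86 on those after LPS. The median standard deviation of a gene between replicates was 0.12 and 0.14 in untreated and LPS input, 0.14 and 0.15 in hnRNP K IP, and 0.47 and 0.76 in Luciferase IP. All 12 arrays share a single estimate of the spread in the planned fit, so these 4 arrays also set the errors of comparisons they are not part of, whose median SE was 0.47 with them and 0.18 without them. For LPS Luciferase IP, the group with the widest spread, the shared estimate was too small for many genes. SEs and adjusted p of comparisons with that group are therefore too small as well.

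**Figure D1:**
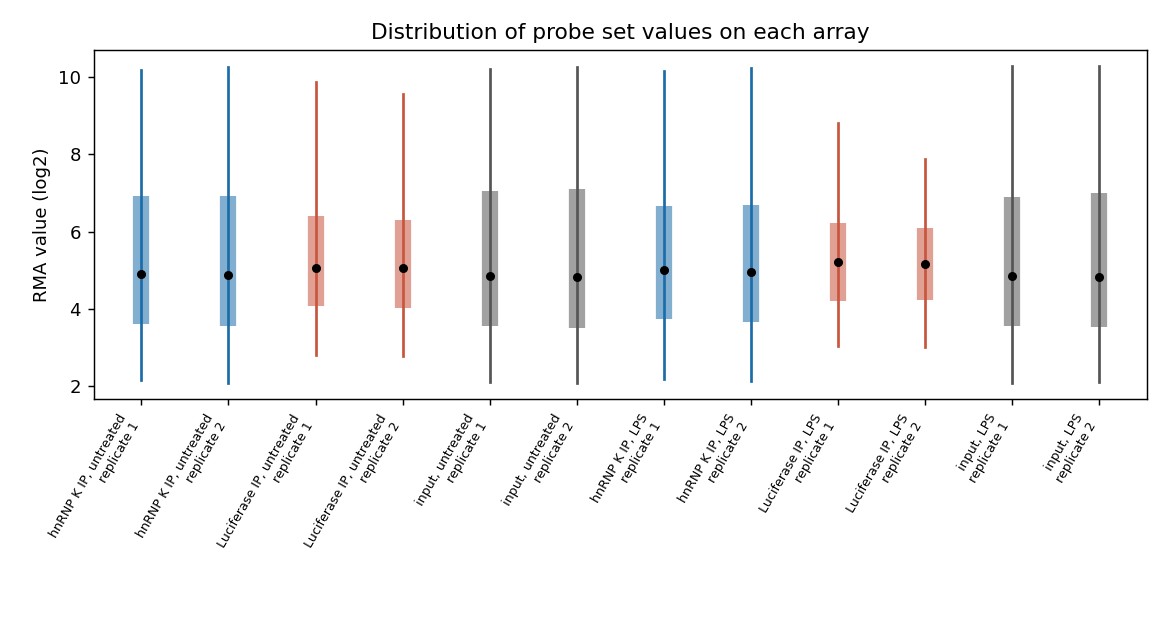
Distribution of RMA values (log2, y axis) over the probe sets of each of the 12 arrays (x axis); the point is the median, the thick bar spans the quartiles and the thin line the 5th to 95th percentile. The medians lie between 4.8 and 5.2, and the 5th to 95th percentile range is narrowest on the LPS Luciferase IP arrays, at 5.79 and 4.86.

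The input arrays show what LPS did to cytoplasmic RNA in these macrophages. Csf3, which encodes granulocyte colony-stimulating factor, was 6.59 ± 0.47 higher after LPS (adjusted p = 0.00115). Il6, an inflammatory cytokine gene, was 6.50 ± 0.79 higher (adjusted p = 0.0139) and Ccl5, a chemokine gene, 5.53 ± 0.29 higher (adjusted p = 0.000172). Socs3, a feedback inhibitor of cytokine signalling, rose by 5.91 ± 0.46 and Gbp2, an interferon-induced GTPase gene, by 6.26 ± 0.73. The untreated levels of Il6 (2.57), Gbp2 (3.50) and Il10 (3.13) in input lay below the lower quartile of those arrays (3.55 and 3.52). The sizes of their 3 differences are uncertain. Among genes that fell, Cd24a, which encodes a surface glycoprotein, changed by -5.57 ± 0.77 (adjusted p = 0.0233). Hpgd, whose enzyme inactivates prostaglandins, changed by -5.00 ± 0.54 (adjusted p = 0.00876), and Tk1, the thymidine kinase of dividing cells, by -2.88 ± 0.41 (adjusted p = 0.0252). Across all genes, which are not independent replicates, the LPS difference in hnRNP K IP correlated with that in input at r = 0.867 (Spearman's rho 0.687, same sign in 72.9% of genes, slope of input on hnRNP K IP 0.778).

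**Figure D2:**
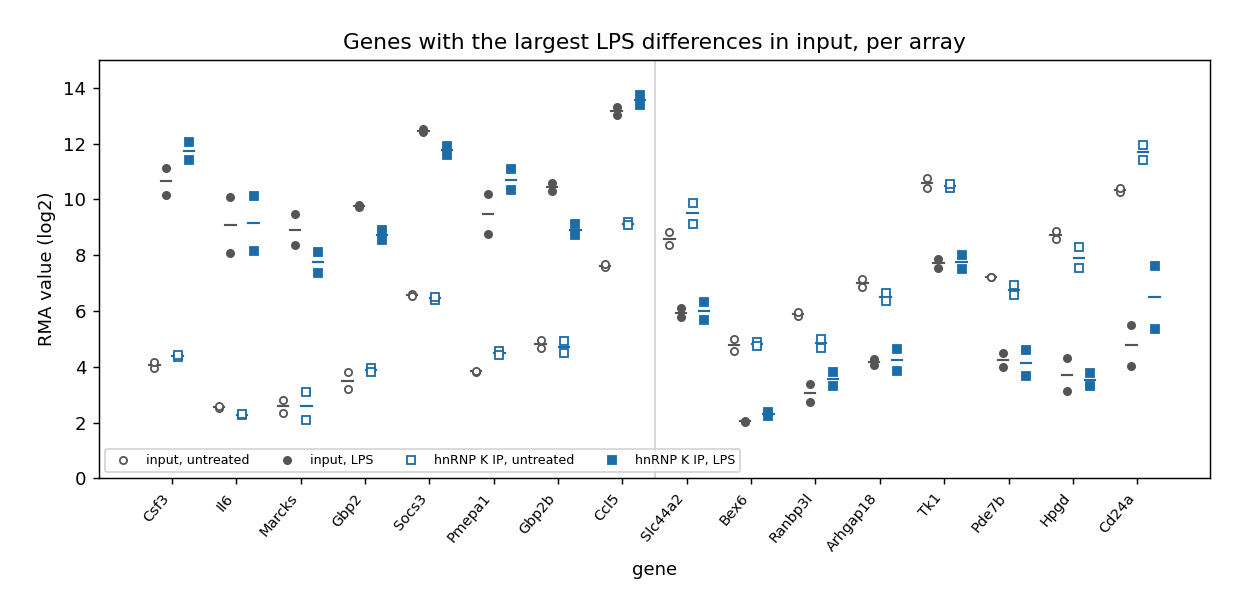
RMA values (log2, y axis) on each input and hnRNP K IP array for the 8 genes with the highest and the 8 with the lowest LPS difference in input (x axis, parted by the grey line); points are single arrays and short lines are means of 2 arrays. The 2 LPS input arrays lie apart from the 2 untreated input arrays for each gene, from Csf3 (6.59 log2 higher) to Cd24a (-5.57 log2).

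Inflammatory genes rose as groups in input. Of 26 measured cytokine and chemokine genes 8 rose and 0 fell, and 21 rose when adjusted over the list alone, with Il10 (4.13 ± 0.47), an anti-inflammatory cytokine gene, beside those above. The list median was 2.94 (camera adjusted p = 3.78e-50). Interferon response genes rose in 7 of 29 cases, 15 adjusted over the list alone, among them Ifit3 (3.81 ± 0.35) and Rsad2 (3.60 ± 0.39), both antiviral effectors (list median 1.53, camera adjusted p = 1.02e-40). NF-kB targets and feedback regulators rose in 2 of 21 cases, Socs3 and Dusp1 (3.34 ± 0.42), a MAP kinase phosphatase gene, and in 12 adjusted over the list alone. Their median was 1.5 (camera adjusted p = 8.79e-30). Of 25 heat shock and immediate early genes, Fosl1 alone rose (2.35 ± 0.39, adjusted p = 0.0475), 4 adjusted over the list alone. The list median was 0.55 (camera adjusted p = 9.13e-09). The cell cycle list shifted down, with a median of -0.77 over 37 genes (camera adjusted p = 4.99e-12), although 0 members passed by themselves in limma over all genes or adjusted over the list alone. These 5 shifts held with an estimated correlation (adjusted p = 0.00106, 0.0111, 0.00106, 0.0246 and 0.0111, in this order).

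Smaller shifts in input concerned signalling and metabolism, and none of them held with an estimated correlation. TLR4 and TAK1 signalling components had a median of 0.32 over 30 genes (camera adjusted p = 0.0043; adjusted p = 0.113 with an estimated correlation), proteasome subunits 0.12 over 34 (0.0108; adjusted p = 0.481 with an estimated correlation), and cholesterol biosynthesis genes -0.41 over 19 (0.00984; adjusted p = 0.22 with an estimated correlation). The published hnRNP K-bound mRNAs had a median of 0.37 over 8 (camera adjusted p = 0.0136; adjusted p = 0.376 with an estimated correlation), and 1 of them rose when adjusted over the list alone. No member of these 4 lists passed over all genes. The other 12 lists did not shift by camera, among them macrophage identity genes (median 0.08), markers of other cell types (0.04), nuclear-retained RNAs (0.08), ribosomal protein genes (-0.01), translation factors (0.05), oxidative phosphorylation (-0.08), lysosome (-0.25), endoplasmic reticulum folding (-0.33), glycolysis (-0.43), hnRNP and poly(C)-binding protein mRNAs (0.02), mRNA stability regulators (0.10) and chromatin regulators (-0.19).

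In all, 43 genes rose and 18 fell with LPS in input by limma, and 1056 had an unadjusted p under 0.05. The 910 that an even spread of p would give is no baseline for this fit. On simulated data, where genes vary independently, 0.01% of unchanged genes had such a p in it. Without the 4 Luciferase IP arrays, a setting chosen after seeing the data, 730 rose and 1416 fell. With the replicate number added as a block, 1435 rose and 2478 fell. The setting without that block included all 61 genes of the planned fit. In that setting 22 of the 26 cytokine genes rose and 1 fell, with Il1b (7.39 ± 1.55 in the planned fit, adjusted p = 2.9e-05 without Luciferase IP), an interleukin gene, and Tnf (1.70 ± 0.47, adjusted p = 0.0205). Of the 37 cell cycle genes 19 fell, including Rrm2 (-2.09 ± 0.66, adjusted p = 0.000192), a subunit of ribonucleotide reductase, and Mcm7 (-1.71 ± 0.87, adjusted p = 0.00221), part of the replicative helicase. The cell cycle shift did not hold in that setting with an estimated correlation (camera adjusted p = 9.98e-11; adjusted p = 0.0631 with an estimated correlation), while the other 4 did. Without untreated input replicate 1 or 2 the planned fit called 6 and 5 genes, and without LPS input replicate 1 or 2 it called 6 and 9. Of 21 genes named in this comparison and called, these left-out arrays ended the call of 17, 18, 17 and 14. Without an LPS Luciferase IP array it called 486, without an untreated one 126, and without an untreated or LPS hnRNP K IP array 23 and 29. The 8-array setting likewise called fewer genes with any single input array left out.

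The comparison of hnRNP K IP with Luciferase IP asks which cytoplasmic RNAs co-purify with hnRNP K beyond the control antibody. In untreated cells Tmem123, which encodes a transmembrane mucin-like protein, was 5.07 ± 0.51 higher in hnRNP K IP (33.7-fold, adjusted p = 0.00306). Snapin, a SNARE-associated protein gene, was 4.99 ± 0.56 higher (adjusted p = 0.00335), and Ube2d1, a ubiquitin-conjugating enzyme gene, 4.64 ± 0.86 higher (adjusted p = 0.0121). Lower in hnRNP K IP were Prpf6, a spliceosome component gene (-3.76 ± 0.53, adjusted p = 0.00535), Mtor, the growth-regulating kinase gene (-2.93 ± 0.31, adjusted p = 0.00306), and Tcof1, which encodes a nucleolar protein (-2.86 ± 0.74, adjusted p = 0.0372). These 3 were brighter in Luciferase IP than in input, at 11.51 against 8.42 for Prpf6, 10.89 against 8.53 for Mtor and 10.56 against 8.95 for Tcof1. Other genes at the low end, such as Cyp3a16 (-3.07 ± 0.46), a cytochrome P450 gene, and Klrb1a (-2.98 ± 0.71), a natural killer cell receptor gene, were dim in hnRNP K IP (1.51 and 2.17) and input (1.57 and 2.31), and their sizes are uncertain.

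The median over all genes was 0.06 for hnRNP K IP against Luciferase IP in untreated cells and 0.37 after LPS. Centring the arrays moved it to 0.23 and 0.58, and quantile normalization to -0.03 and 0.16. For the change of this difference with LPS it was 0.32, 0.37 and 0.18 under the 3 scalings, and for Luciferase IP against input -0.09, -0.30 and 0.04 in untreated cells and -0.33, -0.67 and -0.14 after LPS. For hnRNP K IP against input the 3 medians were 0.06, 0.01 and 0.04 in untreated cells, and 0.14, 0.01 and 0.08 after LPS. List medians in these comparisons are to be read against those values, which cover genes of all levels. For hnRNP K IP against Luciferase IP they are too low for lists of bright genes, since the difference followed input level. In 5 equal groups of genes ordered by input level, its untreated median was 0.81 and 0.61 in groups 4 and 5, the brightest. After LPS it was 1.62 and 2.18. In group 1, the dimmest, it was -0.78 untreated and -1.23 after LPS. For hnRNP K IP against input the medians after LPS were 0.18, 0.25 and 0.22 in groups 1 to 3, and -0.27 and -0.23 in groups 4 and 5. In untreated cells they were 0.084, 0.116 and 0.115, and -0.144 and -0.125. A list median over input near these values does not set the list apart from genes of like level. The camera tests on all genes did not match genes by level.

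Immune genes were among those higher in hnRNP K IP than in Luciferase IP of untreated cells. Of 26 cytokine genes 5 were higher and 0 lower (6 adjusted over the list alone), including Cxcl10 (2.79 ± 0.56), Ccl5 (2.64 ± 0.29) and Ccl3 (1.93 ± 0.28), all chemokine genes. The list median was 0.65 (camera adjusted p = 0.0286; adjusted p = 0.4 with an estimated correlation). TLR4 and TAK1 signalling components had 5 of 30 members higher, also adjusted over the list alone, with Mapk9 (2.65 ± 0.28), which encodes a JNK kinase, Tab3 (2.00 ± 0.35), a TAK1-binding protein gene, and Ticam1 (2.12 ± 0.46), the TRIF adaptor gene. As a list they had a median of 0.88 (camera adjusted p = 0.00102; adjusted p = 0.143 with an estimated correlation). NF-kB targets had 2 of 21 higher, Nfkbie (1.90 ± 0.43) and Zc3h12a (1.72 ± 0.36), and 6 adjusted over the list alone. The median of the list was 0.90 (camera adjusted p = 0.0379; adjusted p = 0.302 with an estimated correlation). Among 24 macrophage identity genes 3 were higher and 2 lower, the latter Cebpb (-1.22 ± 0.31), a myeloid transcription factor gene, and Mertk (-1.63 ± 0.38, of uncertain size at 3.08 in hnRNP K IP), a receptor for dying cells, with 6 higher and 2 lower adjusted over the list alone. Across the list the median was 0.92 (camera adjusted p = 0.0492; adjusted p = 0.24 with an estimated correlation).

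Of the other lists, 4 more shifted up. Ribosomal proteins, translation factors, oxidative phosphorylation and glycolysis did not shift by camera (adjusted p = 0.106, 0.475, 0.56 and 0.145). mRNA stability regulators had 7 of 33 members higher, 8 adjusted over the list alone, among them Zfp36l1 (2.97 ± 0.47), which encodes an AU-rich element binding protein, Tia1 (2.63 ± 0.58), a stress granule protein gene, and Btg2 (2.47 ± 0.51), whose product promotes deadenylation. Their median was 0.85 (camera adjusted p = 0.00439; adjusted p = 0.378 with an estimated correlation). Cholesterol biosynthesis genes had 5 of 19 higher, also adjusted over the list alone, with Sc5d (2.53 ± 0.52), Msmo1 (2.46 ± 0.47) and Insig1 (2.06 ± 0.36). The list median was 1.07 (camera adjusted p = 0.021; adjusted p = 0.302 with an estimated correlation). Lysosome genes had 3 of 29 higher, the cathepsin genes Ctsz (1.72 ± 0.29) and Ctsb (1.02 ± 0.28) and the membrane protein gene Lamp2 (1.49 ± 0.35). As a list they had a median of 0.79 (camera adjusted p = 0.0127; adjusted p = 0.224 with an estimated correlation). Endoplasmic reticulum folding genes had 3 of 24 higher, Pdia3 (2.56 ± 0.53), Canx (1.48 ± 0.42) and Atf6 (1.40 ± 0.36). The median of the list was 0.74 (camera adjusted p = 0.0135; adjusted p = 0.302 with an estimated correlation). Adjusted over the list alone the last 2 lists again had 3 higher each.

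Lists also shifted towards Luciferase IP. Markers of other cell types had 3 of 34 members lower in hnRNP K IP, Apoa1 (-1.51 ± 0.38), Cdh1 (-1.42 ± 0.39) and Lum (-1.08 ± 0.30), and 0 adjusted over the list alone. Across the list the median was -0.39 (camera adjusted p = 0.0135; adjusted p = 0.143 with an estimated correlation). Cdh1 (2.15) and Lum (3.59) were low in hnRNP K IP, so these sizes are uncertain. In Luciferase IP against untreated input 4 of the 34 were higher (camera adjusted p = 0.00272; adjusted p = 0.135 with an estimated correlation). Proteasome subunits had only Psmb3 (-1.81 ± 0.27) lower of 34 (median -0.25, camera adjusted p = 0.0411; adjusted p = 0.654 with an estimated correlation), which also passed adjusted over the list alone. Of 8 published hnRNP K-bound mRNAs 0 passed in limma, over all genes or adjusted over the list alone, and the median of 0.71 was not a shift by camera (adjusted p = 0.265). The list holds Map3k7, which the study itself names, so it is not independent evidence.

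In untreated cells limma called 1474 genes higher and 725 lower in hnRNP K IP than in Luciferase IP (67.0% of them higher), with 168 higher and 95 lower after quantile normalization. With only the arrays of the compared groups it called 0. Leaving out hnRNP K IP replicate 2 gave 0 genes, replicate 1 gave 196, and these ended 63 and 50 of the 63 calls among named genes; Luciferase IP replicates 1 and 2 ended 13 and 14. Arrays outside the comparison also moved the count through the shared spread, to 6451 without an LPS Luciferase IP array and to 1057 without an untreated input array. All 10 list shifts were lost with an estimated correlation, 4 were called among genes above the median level, and 6 and 1 without Luciferase IP replicate 1 and 2.

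After LPS the differences from Luciferase IP were wider. Tmem106c, a transmembrane protein gene, was 5.93 ± 0.44 higher in hnRNP K IP (60.9-fold, adjusted p = 9.35e-05). Bsg, which encodes the surface glycoprotein basigin, was 5.82 ± 0.39 higher (adjusted p = 8.18e-05) and Ddost, a subunit of the oligosaccharyltransferase, 5.72 ± 0.56 higher (adjusted p = 0.000201). Their levels in Luciferase IP were 4.21, 5.01 and 4.97, of which the first lies at the lower quartile of those arrays (4.21 and 4.24), so the fold of Tmem106c is uncertain. At the other end lay genes that are dim in hnRNP K IP and input. Klhl4 (-4.94 ± 0.50, adjusted p = 0.000229) was at 1.71 in hnRNP K IP and 1.59 in input against 6.65 in Luciferase IP. Fshb (-4.19 ± 0.35, adjusted p = 0.000128), a pituitary hormone gene, was at 2.81 and 2.67 against 7. Crh (-4.16 ± 0.45), a hypothalamic hormone gene, and En1 (-4.41 ± 1.05), a homeobox gene, were at 1.58 and 1.60 in LPS input. The sizes of differences from such low levels are uncertain.

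Of the lists, the endoplasmic reticulum folding genes had 17 of 24 members higher, 19 adjusted over the list alone, including Xbp1 (4.43 ± 0.51), a transcription factor of the unfolded protein response, Pdia3 (4.39 ± 0.53) and Manf (4.23 ± 0.37). Their median was 2.17 (camera adjusted p = 7.4e-05; adjusted p = 0.118 with an estimated correlation). Lysosome genes had 21 of 29 higher, 22 adjusted over the list alone, with Ctsz (4.17 ± 0.29), Ctsd (3.09 ± 0.32) and Ctsb (2.78 ± 0.28). The list median was 2.05 (camera adjusted p = 0.000113; adjusted p = 0.118 with an estimated correlation). TLR4 and TAK1 signalling components had 19 higher and 1 lower of 30, 20 and 1 adjusted over the list alone, with the kinase genes Irak2 (2.75 ± 0.34) and Mapk14 (2.73 ± 0.31) and the NF-kB subunit gene Rela (2.25 ± 0.30). As a list they had a median of 2.14 (camera adjusted p = 0.000183; adjusted p = 0.118 with an estimated correlation). Cytokine genes had 18 of 26 higher, 19 higher and 1 lower adjusted over the list alone, with Ccl22 (4.68 ± 0.76), a chemokine gene, and Il10 (3.94 ± 0.47, of uncertain size at 3.98 in Luciferase IP). The median of the list was 2.41 (camera adjusted p = 0.000617; adjusted p = 0.166 with an estimated correlation). Cholesterol biosynthesis genes had 13 of 19 higher, 14 adjusted over the list alone, with Insig1 (3.91 ± 0.36). Across the list the median was 1.86 (camera adjusted p = 0.000524; adjusted p = 0.119 with an estimated correlation).

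Interferon response genes had 14 of 29 members higher after LPS, 18 adjusted over the list alone, with Oasl2 (4.54 ± 0.33) and Mx1 (3.32 ± 0.41), both antiviral. Their median was 1.82 (camera adjusted p = 0.00114; adjusted p = 0.366 with an estimated correlation). mRNA stability regulators had 19 higher and 1 lower of 33, 20 and 1 adjusted over the list alone, led by Zfp36l2 (5.16 ± 0.47), an AU-rich element binding protein gene. The list median was 1.69 (camera adjusted p = 0.0016; adjusted p = 0.316 with an estimated correlation). Macrophage identity genes had 14 higher and 3 lower of 24, 15 and 3 adjusted over the list alone, with Cd68 (4.24 ± 0.53), a macrophage glycoprotein gene. As a list they had a median of 1.80 (camera adjusted p = 0.0279; adjusted p = 0.135 with an estimated correlation). NF-kB targets had 12 of 21 higher, also adjusted over the list alone (median 1.70, camera adjusted p = 0.0103; adjusted p = 0.152 with an estimated correlation). Cell cycle genes had 16 higher and 1 lower of 37, again equal adjusted over the list alone (median 1.43, 0.0103; adjusted p = 0.2 with an estimated correlation), and chromatin regulators 13 of 35 higher in both counts (median 1.51, 0.0241; adjusted p = 0.587 with an estimated correlation). Translation factors had 9 of 31 higher, 8 adjusted over the list alone, with Gspt1 (4.48 ± 0.36), a termination factor gene, and Eif4ebp2 (4.13 ± 0.32), an inhibitor of cap-dependent initiation. The median of the list was 0.92 (camera adjusted p = 0.0279; adjusted p = 0.366 with an estimated correlation). Markers of other cell types had 2 higher and 6 lower of 34, 0 and 4 adjusted over the list alone (median -0.57, camera adjusted p = 0.0111; adjusted p = 0.118 with an estimated correlation), among them Snap25 (-2.72 ± 0.44, of uncertain size at 1.87 in hnRNP K IP), a neuronal SNARE gene. Of the published hnRNP K-bound mRNAs, Eif4e (5.24 ± 1.01), the cap-binding protein gene, Myc (2.45 ± 0.74) and Map3k7 were higher, 3 of 8 in both counts. Across the list the median was 0.88 (camera adjusted p = 0.446). The glycolysis and proteasome medians, 0.81 and 1.06, turned to -0.21 and -0.25 after quantile normalization and were not shifts by camera.

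After LPS limma called 5079 genes higher and 2262 lower in hnRNP K IP than in Luciferase IP, 2303 and 1503 after quantile normalization, and 1556 and 323 with array weights, chosen after seeing the data. With only the arrays of the compared groups it called 0. Leaving out hnRNP K IP replicate 1 or 2 gave 4105 and 3631 genes and ended 6 and 7 of 80 calls among named genes, Luciferase IP replicate 2 ended 4, and the count was 10934 without Luciferase IP replicate 1. On simulated data at the spread of these arrays, 20.3% of unchanged genes had an unadjusted p under 0.05 in this comparison and 521 unchanged genes were called, against 7341 genes called here, so the count overstates the evidence. All 13 list shifts were lost with an estimated correlation, and all were also lost among genes above the median level.

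**Figure D3:**
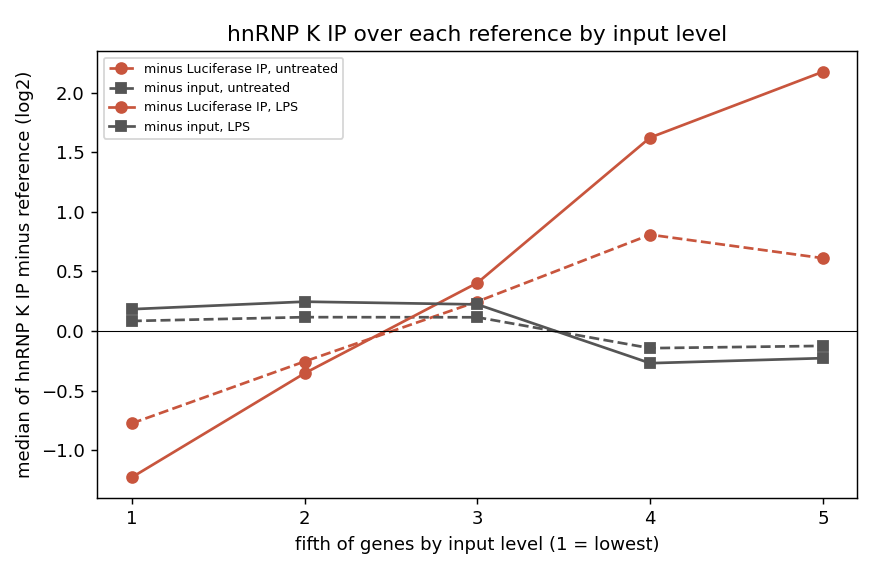
Median over genes of hnRNP K IP minus Luciferase IP (circles) and hnRNP K IP minus input (squares), in log2 (y axis), for 5 equal groups of genes ordered by input level (x axis), untreated (dashed) and after LPS (solid). Over Luciferase IP the medians run from -0.78 to 0.81 in untreated cells and from -1.23 to 2.18 after LPS, while over input they lie between -0.27 and 0.25.

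The difference from Luciferase IP followed the input level of the gene. In untreated cells its median was -0.78 in the fifth of genes dimmest in input and 0.61 in the brightest, and after LPS -1.23 and 2.18. Of the genes higher than in Luciferase IP, 1164 were called in both conditions, where 411.5 were expected of independent lists. The lists share a residual variance per gene and both differences follow input level, so independence is not their value without a shared effect, and the excess may come from either. The overlap was 106 after quantile normalization, 147 and 0 without untreated hnRNP K IP replicate 1 and 2, 623 and 595 without LPS hnRNP K IP replicate 1 and 2, and 2899 and 2697 without LPS Luciferase IP replicate 1 and 2.

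The change of the hnRNP K IP over Luciferase IP difference with LPS was tested as an interaction. Ccdc86, a nucleolar protein gene, gave the highest value, 6.06 ± 0.70 (adjusted p = 0.023). Its level was 8.77 and 9.95 in hnRNP K IP of untreated and LPS cells, and 11.71 and 6.83 in Luciferase IP. Parp2, a DNA damage sensor gene, gave 5.5 ± 0.77, with 9.73 and 9.05 in hnRNP K IP against 11.39 and 5.20 in Luciferase IP. Il6 gave 5.16 ± 1.12, with 2.28 and 9.14 against 3.56 and 5.26, and its untreated values leave the size uncertain. Zfp61, a zinc finger gene, gave -3.93 ± 0.62 (adjusted p = 0.0242) and Rgs18, a regulator of G protein signalling, -3.83 ± 0.87 (adjusted p = 0.0488). Rgs18 was at 1.75 in LPS hnRNP K IP and 3.49 in untreated Luciferase IP, so its size is uncertain.

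By list, 4 of 29 lysosome genes passed the interaction test, 7 adjusted over the list alone, including Atp6v1a (4.25 ± 0.81), a proton pump subunit gene (camera adjusted p = 0.00155; adjusted p = 0.312 with an estimated correlation). Endoplasmic reticulum folding genes passed in 3 of 24 cases, Creld2 (2.70 ± 0.47), Manf (3.08 ± 0.52) and Xbp1 (3.49 ± 0.72), and in 8 adjusted over the list alone (camera adjusted p = 0.000834; adjusted p = 0.312 with an estimated correlation). Cell cycle genes passed in 3 of 37 cases, with Rrm1 (3.27 ± 0.50), and in 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00122; adjusted p = 0.312 with an estimated correlation). The interferon list had Oasl2 (3.08 ± 0.46) alone of 29, 8 adjusted over the list alone. The proteasome list had Psmd12 (2.70 ± 0.52) alone of 34, 2 adjusted over the list alone (for both lists camera adjusted p = 0.000834; adjusted p = 0.451 with an estimated correlation). Cholesterol biosynthesis had Pmvk (2.93 ± 0.47) of 19, 3 adjusted over the list alone (camera adjusted p = 0.0323; adjusted p = 0.451 with an estimated correlation). Chromatin regulators had 2 of 35, Kat6a and Kdm2a, 5 adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.487 with an estimated correlation). Of 8 published hnRNP K-bound mRNAs 0 passed in limma (camera adjusted p = 0.936). Among genes above the median level 0 lists shifted for this change.

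For this change limma called 482 genes positive and 139 negative, with 4097 at an unadjusted p under 0.05. With only the arrays of the compared groups it called 0. With array weights the count was 0, with 1726 at an unadjusted p under 0.05, and it was 0 without any single hnRNP K IP array, which ended all 41 calls among named genes, and 0 without any single input array. On simulated data, where genes vary independently, 14.4% of unchanged genes had an unadjusted p under 0.05 in the planned fit, but it made 0 calls, against 621 here, and recovered 0% of genes changed by 1 or 2 log2 units. The fit with array weights recovered 0 and 1% of them, so its count of 0 tells little. The count of the planned fit also moved with the Luciferase IP arrays. Without untreated Luciferase IP replicate 1 or 2 it was 1170 and 2033, ending 6 and 2 of those calls, and without LPS Luciferase IP replicate 1 or 2 it was 7265 and 4007.

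Map3k7, which encodes TAK1, the kinase named in the title of the series, was represented by the brightest of its 6 probe sets. Its level was 7.96 in hnRNP K IP, 6.69 in Luciferase IP and 8.12 in input of untreated cells, and 6.90, 5.70 and 7.40 after LPS. It was 1.27 ± 0.40 higher in hnRNP K IP than in Luciferase IP of untreated cells, which did not pass (adjusted p = 0.0691), and 1.2 ± 0.40 higher after LPS, which did (adjusted p = 0.0372; 0.363 with array weights). The change with LPS was -0.07 ± 0.56 (adjusted p = 0.96). For this change, for hnRNP K IP against input and for LPS in input, the planned fit recovered 0% of simulated genes changed by 2 log2 units. Not passing in those comparisons thus tells little about Map3k7. Against input it was -0.16 ± 0.40 and -0.50 ± 0.40 in the untreated and LPS hnRNP K IP (adjusted p = 1 and 0.921), and -1.42 ± 0.40 and -1.70 ± 0.40 in Luciferase IP (adjusted p = 0.0493 and 0.00722). In input it differed by -0.71 ± 0.40 with LPS (adjusted p = 1), while the 3 next brightest probe sets of the gene gave 0.42, 0.25 and 0.64. Over Luciferase IP these 3 gave 1.88 ± 0.54, 0.75 ± 0.31 and 0.54 ± 0.52 in untreated cells, and 3.19 ± 0.54, 0.62 ± 0.31 and -0.59 ± 0.52 after LPS, and a dim one gave -0.93 ± 0.71 and -1.49 ± 0.71.

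The mRNA of hnRNP K itself (Hnrnpk) was 1.03 ± 0.74 above Luciferase IP in untreated cells (adjusted p = 0.403) and 2.12 ± 0.74 after LPS (adjusted p = 0.0464; 0.25 with array weights). Over input it was 0.73 ± 0.74 and 0.40 ± 0.74, which did not pass (adjusted p = 1 and 0.988). As for Map3k7, not passing over input in the planned fit tells little. In input Hnrnpk differed by 0.23 ± 0.74 with LPS (adjusted p = 1). These values are of its brightest probe set. The others gave 1.24 ± 0.73, 0.82 ± 0.46 and 0.64 ± 0.61 over Luciferase IP in untreated cells, and 3.42 ± 0.73, 2.22 ± 0.46 and 1.89 ± 0.61 after LPS. Over input they gave 0.92, 0.70 and 0.49 in untreated cells, and 0.70, 0.56 and 0.40 after LPS, with the same SEs.

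Input gives a second reference for hnRNP K IP, with steadier arrays. The planned fit called 0 genes in either condition by limma, with 920 and 1594 at an unadjusted p under 0.05. The member counts and limma adjusted p below come from the fit without the 4 Luciferase IP arrays, chosen after seeing the data. They stand beside the SE of the planned fit. Camera adjusted p, also with an estimated correlation, come from the planned fit unless another fit is named. In untreated cells Trp53bp1, a DNA repair scaffold gene (-2.76 ± 0.41, adjusted p = 0.00283), Numa1, a spindle protein gene (-2.41 ± 0.40, adjusted p = 0.00279), and Taf1, a subunit of the general transcription factor TFIID (-2.17 ± 0.35, adjusted p = 0.00279), were lower in hnRNP K IP than in input. After LPS Trp53bp1 (-2.93 ± 0.41) and Taf1 (-2.27 ± 0.35) were again lower, with Cog7 (-1.91 ± 0.31), a Golgi complex gene (each adjusted p = 0.000936). Cog7 was at 3.34 in hnRNP K IP, so its size is uncertain. In the planned fit these genes had an adjusted p of 0.518 in untreated cells and 0.208 after LPS.

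The members named next were chosen after their values were seen. Proteasome subunits were lower than in input in 17 of 34 cases in untreated cells and 25 after LPS, with 0 higher, and in 2 and 5 in the planned fit adjusted over the list alone. Psmd12 was at -1.5 ± 0.36 and -1.49 ± 0.36 (adjusted p = 0.00279 and 0.000936) and Psmc1 at -1.26 ± 0.31 and -1.54 ± 0.31. The list medians were -0.70 and -0.77 (camera adjusted p = 3.12e-14 and 4.15e-12 in the planned fit; adjusted p = 0.174 and 0.129 with an estimated correlation). Chromatin regulators were lower in 15 and 22 of 35 cases, with the histone methyltransferase gene Kmt2d at -1.81 ± 0.61 after LPS. Their medians were -0.63 and -1.01 (camera adjusted p = 7.58e-07 and 9.49e-10; adjusted p = 0.283 and 0.154 with an estimated correlation). hnRNP and poly(C)-binding protein mRNAs were lower in 7 and 14 of 26 cases and higher in 2 and 0, with Hnrnpm at -1.76 ± 0.59 and -2.21 ± 0.59. The list medians were -0.47 and -0.82 (camera adjusted p = 0.000249 and 4.98e-07; adjusted p = 0.461 and 0.194 with an estimated correlation). Cell cycle genes were lower in 12 and 19 of 37 cases and higher in 1 and 1, with the motor protein gene Kif11 at -1.45 ± 0.61 and -1.47 ± 0.61. As a list they had medians of -0.39 and -0.75 (camera adjusted p = 0.00593 and 6.23e-07; adjusted p = 0.269 and 0.129 with an estimated correlation).

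Glycolysis genes were lower in 5 and 9 of 18 cases and higher in 2 and 2 (medians -0.45 and -0.60, camera adjusted p = 0.0119 and 0.000772; adjusted p = 0.283 and 0.129 with an estimated correlation), and interferon response genes lower in 5 and 15 of 29 and higher in 1 and 1. Their medians were -0.37 and -0.72 (camera adjusted p = 0.0143 and 0.000131; adjusted p = 0.509 and 0.235 with an estimated correlation). After LPS 4 more lists shifted down. These were NF-kB targets with 9 lower and 2 higher of 21 (median -0.41, camera adjusted p = 0.0178; adjusted p = 0.17 with an estimated correlation) and heat shock and immediate early genes with 9 and 2 of 25 (-0.55, 0.00251; adjusted p = 0.154 with an estimated correlation). The others were translation factors with 12 lower and 3 higher of 31 (median -0.26) and mRNA stability regulators with 11 and 0 of 33 (-0.27). Their camera adjusted p were 0.00683 and 0.00545, and 0.235 and 0.293 with an estimated correlation. Both medians lay near the -0.23 and -0.27 of all genes in groups 5 and 4 by LPS input level, so they do not show lower recovery than genes of like level.

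Lists higher than in input were fewer. For 3 of them the camera adjusted p were larger without Luciferase IP, in untreated and LPS cells, than in the planned fit. They were 0.0116 and 0.0345 for lysosome genes, 0.0216 and 0.0316 for macrophage identity genes, and 0.00361 and 0.0191 for cytokine genes. Lysosome genes were higher in 5 and 7 of 29 cases and lower in 2 and 3, with Ctsb at 1.10 ± 0.28 and 1.21 ± 0.28. The list medians were 0.47 and 0.44 (camera adjusted p = 0.00302 and 0.00545; adjusted p = 0.174 and 0.129 with an estimated correlation). Macrophage identity genes were higher in 4 and 6 of 24 cases and lower in 0, with Cd68 at 1.47 ± 0.53 and 1.53 ± 0.53 and Fcer1g, an Fc receptor chain gene, at 0.87 ± 0.37 and 0.79 ± 0.37. As a list they had medians of 0.22 and 0.35 (camera adjusted p = 0.0171 and 0.0138; adjusted p = 0.174 and 0.129 with an estimated correlation). Cytokine genes were higher in 5 and 7 of 26 cases and lower in 0, with Cxcl10 at 1.51 ± 0.56 and 0.83 ± 0.56. Their medians were 0.32 and 0.45 (camera adjusted p = 0.00035 and 0.0043; adjusted p = 0.269 and 0.207 with an estimated correlation). After LPS endoplasmic reticulum folding genes were higher in 5 of 24 cases, with the chaperone gene Calr at 1.23 ± 0.58 (median 0.34, camera adjusted p = 0.0456, 0.0993 without Luciferase IP; adjusted p = 0.293 with an estimated correlation). Markers of other cell types were higher in 4 of 34, against 1869 of all 18193 genes. Their median was 0.29 (camera adjusted p = 0.0194, and 0.129 with an estimated correlation). That lies near the 0.25 of all genes in group 2 by LPS input level, so it does not set these dim genes apart.

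**Figure D4:**
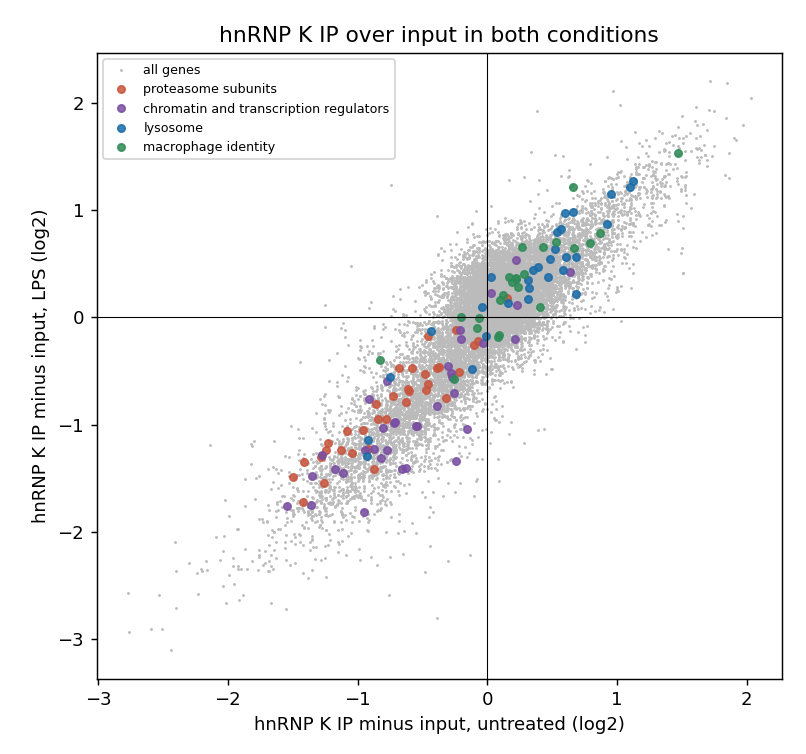
hnRNP K IP minus input (log2) in untreated cells (x axis) against the same difference after LPS (y axis) for 18193 genes (grey), with the members of 4 lists in colour. The points follow a line (r = 0.867 across genes), with the median of proteasome subunits at -0.70 and -0.77 and of lysosome genes at 0.47 and 0.44.

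Without the Luciferase IP arrays 965 genes were higher and 1577 lower than in input in untreated cells, and 1869 and 2812 after LPS. In both conditions 759 were higher and 1468 lower, where 99.1 and 243.7 were expected of independent lists, and 0 and 1 were called in opposite directions. These lists too share a residual variance per gene, which may raise the overlap. With the replicate number as a block, chosen after seeing the data, 2058 were higher and 2733 lower in untreated cells, and 3611 and 3747 after LPS. The next counts, with an array left out, come from the fit without Luciferase IP arrays and without that block. Without untreated hnRNP K IP replicate 1 or 2 this fit called 2553 and 744 genes, and without untreated input replicate 1 or 2 it called 503 and 917. After LPS the 4 counts were 2907, 3148, 3187 and 2473, in the same order. Of 15 list shifts over input after LPS 9 were called among genes above the median level. Across genes, the untreated and LPS differences over input correlated at r = 0.867 (Spearman's rho 0.746, same sign in 80.4% of genes), with no array shared.

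Genes above both references, Luciferase IP and input, numbered 0 in each condition by limma in the planned fit, since 0 passed against input at any size. By limma 484 and 505 passed against both with array weights, chosen after seeing the data, where 82.3 and 166.7 were expected of independent lists. Both comparisons share the hnRNP K IP arrays, so part of the excess may come from them. In simulated groups without any difference 0 genes passed both with array weights, but 0 passed against Luciferase IP alone. With large shifts given to genes drawn independently for each reference, 522 and 503.3 passed both in untreated and LPS cells, where 517.2 and 509.2 were expected, which leaves calls near the threshold untested. Without LPS Luciferase IP replicate 1 or 2 the planned fit gave 194 and 190 genes in LPS cells, and without either of them 782 differed from input, 201 higher and 581 lower.

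The change of the hnRNP K IP over input difference with LPS passed for no gene. Ccl12, a chemokine gene, had 1.97 ± 0.66, Ranbp3l 1.54 ± 0.55 and Zfp935 -1.61 ± 0.58, with adjusted p = 1, and 0.913 without the Luciferase IP arrays. Each was low in at least 1 group (Ccl12 at 2.87 in untreated hnRNP K IP, Ranbp3l at 3.07 in LPS input, Zfp935 at 3.08 in LPS hnRNP K IP), so their sizes are uncertain. limma called 0 genes, with 14 at an unadjusted p under 0.05. Without the Luciferase IP arrays it called 0 with 887, and with array weights 0 with 905, where 910 were expected by chance. That number is no baseline for the 14, since on simulated data 0.03% of unchanged genes had such a p in the planned fit. With the replicate number as a block in the fit without Luciferase IP it called 0 with 2009, and the smallest adjusted p was 0.209. By camera 11 lists shifted, 10 of them down, led by cell cycle genes (median -0.35, camera adjusted p = 9.5e-07; adjusted p = 0.12 with an estimated correlation), with 0 members called, and 0 lists did so with an estimated correlation. Without untreated hnRNP K IP replicate 2 or LPS input replicate 2, 7 lists shifted. On simulated data the fit without the Luciferase IP arrays recovered 43% of genes changed by 1 log2 unit and 100% of those changed by 2, and the planned fit 0% of both.

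Luciferase IP differed from input as well. In untreated cells Ccdc86 (3.77 ± 0.50), Parp3 (3.24 ± 0.69) and Rsph4a (3.18 ± 0.38) were higher in Luciferase IP, and Eea1 (-4.72 ± 0.69), an early endosome protein gene, Fcho2 (-4.4 ± 0.76), an endocytosis gene, and Dnajc21 (-4.37 ± 0.98) were lower. Rsph4a was at 2.04 in input and Fcho2 at 3.99 in Luciferase IP, so their sizes are uncertain. After LPS Klhl4 (5.06 ± 0.50), En1 (4.4 ± 1.05) and Plppr4 (4.34 ± 0.75) were higher, from input levels of 1.59, 1.60 and 2.36 that leave the sizes uncertain. Lower were Cetn2 (-5.76 ± 0.62), a centrosome gene, Rnmt (-5.57 ± 0.88), the cap methyltransferase gene, and Trappc8 (-5.54 ± 0.59, of uncertain size at 3.89 in Luciferase IP). limma called 760 genes higher and 1270 lower in untreated cells, and 2871 and 5900 after LPS. On simulated data 19.3% of unchanged genes had an unadjusted p under 0.05 after LPS and 399 unchanged genes were called, against 8771 genes called here, so the LPS counts overstate the evidence. Markers of other cell types were higher in 4 of 34 cases in untreated cells, and in 8 with 1 lower after LPS, while mRNA stability regulators were lower in 8 of 33 cases in untreated cells, and in 24 with 2 higher after LPS. In untreated cells 5 lists shifted by camera and after LPS 16, and 0 of them did so with an estimated correlation; among genes above the median level 1 and 3 shifted. Without untreated input replicate 1 or 2 the untreated count was 0, which ended all 7 calls among named genes, and without Luciferase IP replicate 1 it was 3473 and ended 1, as replicate 2 did. It was 6844 without an LPS Luciferase IP array and 868 without an LPS input array. After LPS the count was 5263 and 4849 without input replicate 1 or 2, the former ending 1 of 7 calls.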

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

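Genes whose difference between hnRNP K IP and Luciferase IP changed with LPS are given here because the interaction test called 621 of them. The test on array weights below was chosen after the result was seen, and the other tests were written down before. Positive values were 6.06 for Ccdc86, 5.50 for Parp2, 5.24 for Supt6 and 5.17 for Kat6a, 5.16 for Il6, 4.78 for Gspt1, 4.67 for Kdm2a, 4.62 for Ccl12 and 4.25 for Atp6v1a. Smaller positive values were 3.49 for Xbp1, 3.27 for Rrm1, 3.08 for Manf, 3.08 for Oasl2, 2.93 for Pmvk, 2.70 for Creld2, 2.70 for Psmd12, 2.67 for Bub1b, 2.57 for Ctsd, 2.45 for Ctsz and 2.08 for Cenpa. Negative values were -3.93 for Zfp61, -3.83 for Rgs18, -3.77 for Pgm5, -3.58 for Zdhhc9, -3.56 for Pld6, -3.54 for Abo, -3.51 for H2bc21 and -3.47 for Bex6. At least 1 group mean lay below the lower quartile of its arrays for Supt6, Il6, Ccl12, Rgs18, Zdhhc9, Pld6, Abo and Bex6, so the sizes of these changes are uncertain. Over Luciferase IP the list medians of this change were 1.83 for cell cycle, 1.62 for interferon response, 1.45 for endoplasmic reticulum folding, 1.42 for cholesterol biosynthesis, 1.34 for chromatin regulators, 1.23 for lysosome and 1.22 for proteasome.

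For this change 2 explanations were weighed. With array weights the number of genes called was 0, with the same differences of means, but on simulated data this fit recovered 1% of genes changed by 2 log2 units. The planned fit made 0 calls among simulated genes that vary independently at the spread of these arrays, against 621 here. These values leave open whether the spread of the Luciferase IP arrays made the calls. A change of hnRNP K association with LPS should also appear over input. Among the called genes the median change over input, turned to the sign of the change over Luciferase IP, was -0.043 against 2.668. That median over input lay between -0.107 and 0.011 with any array left out. These values argue against a change of association of that size for the called genes as a set. The genes were picked by their change over Luciferase IP, so smaller changes of association were not tested by this. For the called genes as a set, the change over Luciferase IP lay in the Luciferase IP arrays relative to input.

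The differences of hnRNP K IP from Luciferase IP within each condition were weighed in the same way. Across genes, Spearman's rho of input level with this difference was 0.569 in untreated cells and 0.786 after LPS, as a low RNA content of the Luciferase IP arrays would give. The mean r with input of the same condition was 0.971 to 0.984 for hnRNP K IP arrays and 0.562 to 0.890 for Luciferase IP arrays. With hnRNP K IP so close to input, its difference from arrays of narrow range rises with input level whatever the antibody recovered. The rho therefore cannot decide between the explanations. Selective recovery by the hnRNP K antibody was tested by the partial rho of the untreated difference over Luciferase IP with the LPS difference over input, given untreated input: 0.279 lay between the bounds of 0.3 and 0.1 set beforehand and cannot tell. The amount of RNA recovered in each IP is not given in the sources used here.

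Among genes above the median level, those with a long genomic span lay below input in hnRNP K IP, with a partial rho of -0.298 in untreated cells and -0.329 after LPS, across 9087 genes. Span correlated with Luciferase IP minus input at -0.199 in untreated cells, as a loss of long RNAs in any immunoprecipitation would give. It also correlated at -0.108 with LPS minus untreated input, given the level in untreated hnRNP K IP, although that difference involves no immunoprecipitation. The sign of that value follows the order of subtraction in an LPS response, so it is no baseline for differences between IP and input. The hnRNP K IP and Luciferase IP differences in a condition share the input arrays. These values therefore cannot assign the pattern to the immunoprecipitation step. Span correlated with hnRNP K IP minus Luciferase IP at -0.004, where a lower recovery by the hnRNP K antibody would give a negative value. Genomic span is not the length of the mRNA, and genes are not independent replicates.

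Over input, list medians of the LPS-dependent change differed from the other genes by camera: -0.35 for cell cycle, -0.30 for hnRNP and poly(C)-binding protein mRNAs, -0.27 for heat shock and immediate early genes, -0.27 for cholesterol biosynthesis, -0.26 for chromatin regulators, -0.22 for glycolysis, -0.21 for interferon response, -0.21 for TLR4 and TAK1 signalling, -0.18 for translation factors, -0.17 for mRNA stability regulators and 0.17 for markers of other cell types. None of these held with an estimated correlation, and 0 members passed in limma. Of 10092 probe sets without a single gene symbol, which the gene tests did not use, 219 were higher and 936 lower in hnRNP K IP than in Luciferase IP of untreated cells, and 700 higher and 3002 lower after LPS.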

How the results depend on the processing

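Array weights, the fits without Luciferase IP and leaving out arrays outside a comparison were added after seeing the data, the other settings before. Genes called in hnRNP K IP against Luciferase IP, untreated (2199), numbered 263 after quantile normalization and 0 with only the compared groups. After LPS (7341) they numbered 3806, 0, and 1879 with array weights. The LPS-dependent change over Luciferase IP (621) fell to 0 with only the compared groups and 0 with array weights. LPS in input (61) gave 16 after quantile normalization, 99 with the mean of probe sets, 2357 with only the compared groups, 2857 with array weights and 2146 without Luciferase IP. hnRNP K IP against input (0) gave 2278, 3207 and 2542 under the last 3 settings in untreated cells, and 3727, 4898 and 4681 after LPS. Luciferase IP against input, untreated (2030), gave 73 after quantile normalization, 1179 among genes above the median level and 0 with only the compared groups, and after LPS (8771) 3828 after quantile normalization, 1990 with only the compared groups and 2729 with array weights. Genes above both references (0 and 0) numbered 484 and 505 with array weights, and the overlap of 1164 became 106 after quantile normalization and 582 with array weights. The larger counts without Luciferase IP arise with the median SE of 0.18 against 0.47; for the other changes the cause was not tested.

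With an array of the compared groups left out, where the lone remaining array is assumed to vary like the other groups, the counts ran from 0 to 3020 and 3631 to 10934 for hnRNP K IP against Luciferase IP (untreated, LPS), 0 to 7265 for its change, 5 to 9 for input, 0 to 0 for hnRNP K IP against input in each condition and for its change, 0 to 3473 and 4849 to 11561 for Luciferase IP against input, 0 to 0 and 0 to 194 above both references, and 0 to 2899 for the overlap. With an array outside the compared groups left out, hnRNP K IP against input after LPS gave 782 without either LPS Luciferase IP array and otherwise 0, it gave 0 in untreated cells and for its change, and the change over Luciferase IP gave 0.

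List shifts by camera in hnRNP K IP against Luciferase IP, untreated (10), numbered 0 with an estimated correlation, 3 after quantile normalization, 4 among genes above the median level, and 1 to 9 with an array left out. In the same order they were 0, 4, 0 and 11 to 16 after LPS (13; 20 by fry), and 0, 3, 0 and 5 to 10 for the change (7; 12 by fry). In input (9) they were 5 with an estimated correlation, 5 by fry and 7 to 10 with an array left out. For hnRNP K IP against input, untreated (9), they were 0, 0 and 9 to 10, after LPS (15) 0, 3 and 12 to 14, with 9 among genes above the median level, and for the change (11) 0, 0 and 7 to 12. For Luciferase IP against input, untreated (5), they were 0 with an estimated correlation, 8 by fry, 0 after quantile normalization, 1 among genes above the median level and 4 to 6 with an array left out, and after LPS (16) 0 with an estimated correlation, 4 after quantile normalization, 3 among genes above the median level and 15 to 16 with an array left out.

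Of 3642 values of named genes under the alternatives, 2659 stayed on their side of the threshold, 900 lost the call, 76 gained it and 7 reversed. Trem2 in untreated cells was -0.108 over Luciferase IP without probe sets prone to cross-hybridization. After LPS quantile normalization gave Bub1b -1.467, Aldoc -0.335, Pfkp -0.084 and Mpeg1 -0.069, and the mean of probe sets gave Med13 -0.163 and Psmb3 0.869; the cause was not tested.

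The replicate numbers are not described as pairs. With the replicate number as a block the 9 gene counts were 2314, 7541, 705, 66, 0, 0, 0, 2268 and 9007, in the order of the comparisons given above, and none of these moved over 1.5-fold. Deviations of replicate 1 from replicate 2 correlated between groups at 0.00807 to 0.570 over 15 pairs of groups, 11 of them over 0.1, and at 0.258 to 0.570 over the 6 pairs without Luciferase IP, a hint of pairing from the data and not from the design. Without Luciferase IP the block raised the counts from 2146 to 3913 for input, from 2542 to 4791 and from 4681 to 7358 for hnRNP K IP against input, and left 0 for its change, with 2009 at an unadjusted p under 0.05 against 887. The C-rich 3' untranslated region analysis was not run, since no transcript sequences were used here. Signal over background limits dim genes most, and the Luciferase IP arrays had the fewest probe sets above 8.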

Other observations

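Several genes outside the lists' leading members are given here, all chosen after their values were seen. The limma adjusted p of this section come from the fit without Luciferase IP arrays, while each ± is the SE of the planned fit. In the fit without Luciferase IP arrays, Eif4ebp2, a translation inhibitor gene, was 1.67 ± 0.32 above input in hnRNP K IP of untreated cells and 1.61 ± 0.32 above after LPS (limma adjusted p = 0.00279 and 0.000887). Nuclear-retained RNAs did not shift as a list by camera (adjusted p = 0.323 and 0.463). Norad, a noncoding RNA that binds Pumilio proteins, lay at -0.91 and -0.96 (limma adjusted p = 0.0141 and 0.00651). It was placed on that list beforehand, which does not show that it is retained in the nucleus. Ribosomal protein genes had medians of 0.05 and 0.09 over input (camera adjusted p = 0.159 and 0.278).

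In the input arrays, without the Luciferase IP arrays, LPS raised Myc, a growth transcription factor gene, by 3.03 ± 0.74 (limma adjusted p = 2.15e-05) and Zfp36, whose product destabilizes cytokine mRNAs, by 2.36 ± 0.49 (limma adjusted p = 0.000415). Eno2, a glycolytic enzyme gene, fell by 2.16 ± 0.45 (limma adjusted p = 0.000811) and Dhcr7, of cholesterol synthesis, fell by 1.08 (limma adjusted p = 0.0096).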
